A study of Rattus norvegicus with 10 samples.

How the data were processed

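Gene expression in the vastus lateralis, a thigh muscle, of male Fischer-344 rats was measured on Illumina RatRef-12 expression beadchips, 1 array per animal. There were 5 calorie-restricted (CR) animals and 5 fed ad libitum (AL), and each array was placed in its group by the diet in its title. AL array 10 lacks diet and tissue among its tagged characteristics, and its title and description give the diet. Replicate numbers run from 1 to 5 in CR and from 6 to 10 in AL, so no number is shared between the diets. No slide, scan date or batch was given in the sources used here.

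The deposited values are z-scores: per the labels' series design text, the authors extracted the fluorescent signals with GenomeStudio Gene Expression 1.6.0, removed spots at or below background with a detection p limit of 0.02, took natural logs and standardised each array by its own mean and standard deviation. The deposited table has 22517 rows, of which 11293 hold a score in all 10 arrays and 11224 are blank in all 10. Over the 11293 listed probes, each array's scores had a mean of 0.556 to 0.620 and an SD of 1.10 to 1.17, so the standardisation was not made on the listed probes alone. If it was made on all rows, the blank rows would have had mean scores between -0.623 and -0.559 with an SD of 0.104 to 0.119. Distances of the identified probes from this implied level were computed after seeing the data. A score difference of 1 equals 1 SD of an array's own natural log signals. That SD is not given in the sources used here, so no score difference can be turned into a fold change. Standardisation equalises the mean and SD of each array but not the shape of its distribution.

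Rows are identified by a running number from 1 to 22517. No file used here pairs these numbers with probes or genes, and none of the listed numbers matched a gene identifier of the rat gene table at hand (assembly GRCr8). Gene names, positions and annotations are therefore not reported, and the 34 gene lists and the cell type markers fixed beforehand could not be tested. The rule for named genes asked for the 12 largest called, non-overlapping differences in each direction. It was applied to rows instead of genes: the 12 rows per direction are summarised, and the 2 largest per direction are identified by row number. Its parts on gene lists and on specific genes could not be used.

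Scores were tested as deposited with limma 3.58.1 in R 4.3.3: a linear model per probe with diet as its only term, empirical Bayes moderation, a two-sided test of CR minus AL and Benjamini-Hochberg adjustment over all 11293 probes. A probe was called at an adjusted p under 0.05. Errors of differences are limma's standard errors. Similarity between arrays was Pearson's r over the listed probes. The mean r within diets minus that between diets was compared with all 126 ways to divide the arrays into 5 and 5, and group means of single values were compared over all 252 assignments, as exact permutation tests. No pair of arrays shared an identical score at any probe, so the 10 arrays were counted as 10 samples. The design text says that 5 animals were used per diet, so each array is taken as 1 animal.

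The number of arrays limits the precision. The procedure was tested on simulated data for the CR against AL comparison, with 11293 probes, 200 of them changed. Levels were the observed probe means. Noise was normal and independent between probes, with limma's moderated variances. Of the changed probes, 52.9% were called at a simulated difference of 0.25, 95.5% at 0.5 and 100% at 1, with 5 false calls. A simulation without any change gave 0 calls. Neither simulation held correlated probes or an array that stood apart, so these rates may not hold for the real arrays.

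Choices made before the data were examined were the test, the threshold, the rule for named genes and these alternatives: quantile normalization, median centring, median centring with scaling by the median absolute deviation (MAD), a filter to probes above the median level, an intensity trend in the prior variance with and without robust estimation, array weights, an unmoderated equal-variance statistic, other thresholds and the removal of each array. Cyclic loess, quantile normalization without AL array 10 and the joint removal of CR array 5 and AL array 10 were added after seeing the data. The comparison of array correlations and principal components was not among the tests fixed beforehand, and its other settings, the split of probes by level and the comparison of probes with a mean score above 4, with its test, were chosen after seeing the data.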

Results

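Transcript levels were compared in the vastus lateralis of 27-month-old male Fischer-344 rats that had eaten either without limit or on a restricted ration since 2 months of age. The restricted ration was brought down stepwise to 40% calorie restriction. The series title places this comparison beside human muscle, which was not analysed here. There were 10 arrays, 5 from CR animals (numbered 1 to 5) and 5 from AL animals (numbered 6 to 10). Each gave a score for the same 11293 probes. A score is a probe's natural log signal in SDs of its own array, and differences between diets are given in these units.

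The muscle transcriptomes resembled each other more within a diet than between diets. The mean correlation was 0.985 over the 10 pairs of CR arrays, 0.981 over the 10 pairs of AL arrays and 0.976 over the 25 pairs across diets. The within-diet mean exceeded the between-diet mean by 0.0065, more than for any other way to divide the 10 arrays into 5 and 5 (exact permutation test, one-sided, p = 0.0079 over 126 divisions). On the first principal component, which held 34.8% of the variance, the CR arrays scored -7.85 ± 3.41 (SD, n = 5) and the AL arrays 7.85 ± 8.98 (SD, n = 5), without overlap (exact permutation test, two-sided, p = 0.0079, the smallest that 5 against 5 arrays allow). This component also set AL array 10 apart, at 22.19, while the other AL arrays scored from 0.65 to 10.79. It was not recomputed without AL array 10, so its share of variance is not that of diet alone. AL array 10 had the lowest mean correlation with its own diet, 0.969, and CR array 5 had the lowest among the CR arrays, 0.978. The within-diet excess stayed at p = 0.040 or below when any one array was left out (exact permutation test).

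**Figure D1:**
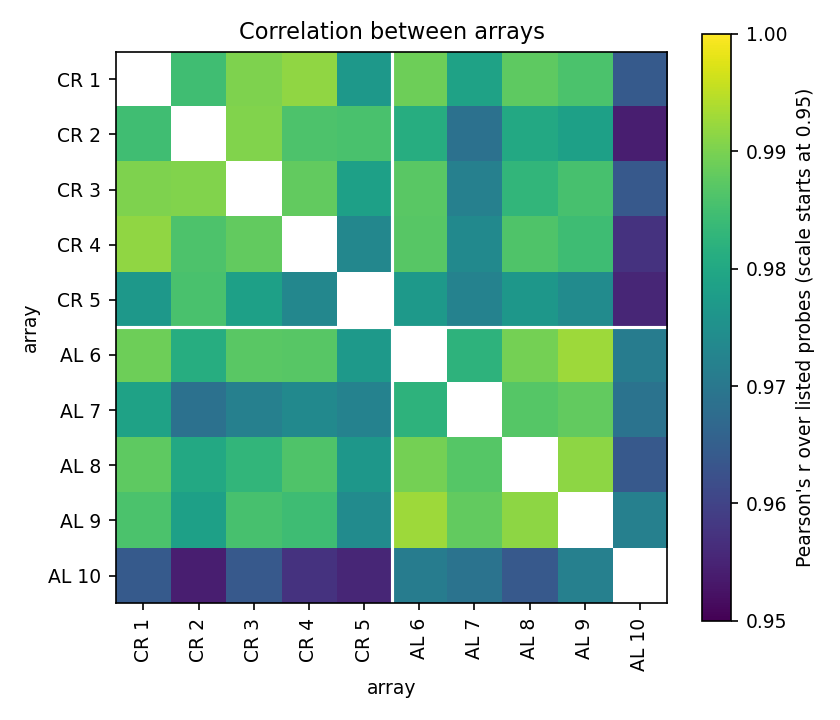
Pearson's r between each pair of arrays over the 11293 listed probes, CR arrays 1 to 5 and AL arrays 6 to 10, on a colour scale that starts at 0.95 with the diagonal left blank. White lines part the diets, and AL array 10 stands out with its low values, down to 0.954 across diets.

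Between the diets, 155 of the 11293 probes differed, 44 of them higher and 111 lower in CR than in AL muscle (limma, Benjamini-Hochberg adjusted p under 0.05). The median size of these differences was 0.43 among probes higher in CR and 0.29 among probes lower in CR. Of the 155 probes, 22 differed by over 0.5. Most of the called probes, 135 of 155, lay above the median level of all probes. At an unadjusted p under 0.05 there were 2546 probes, 926 higher and 1620 lower in CR. The 5 CR and the 5 AL scores did not overlap at 680 probes, or 6.02% of those listed. Chance gives 0.794% on average over all 252 assignments, and the spread of this share between assignments is not given here. Of these 680 probes, 231 were higher and 449 lower in CR.

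The split into higher and lower calls depended on how the arrays were scaled and on single arrays. With the deposited scores 71.6% of the calls were lower in CR. After quantile normalization there were 81 calls, 40 higher and 41 lower, or 50.6% lower, and 74 of them were among the 155. With median centring and scaling by the median absolute deviation the split was 18 higher and 7 lower, or 28% lower. Leaving out 1 array at a time gave 52, 23, 36, 53 and 182 calls without CR arrays 1, 2, 3, 4 and 5, and 94, 55, 71, 41 and 258 calls without AL arrays 6, 7, 8, 9 and 10. Over these removals the share lower in CR ranged from 47.8% without CR array 2, with 12 probes higher and 11 lower, to 73.2% without AL array 8.

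**Figure D2:**
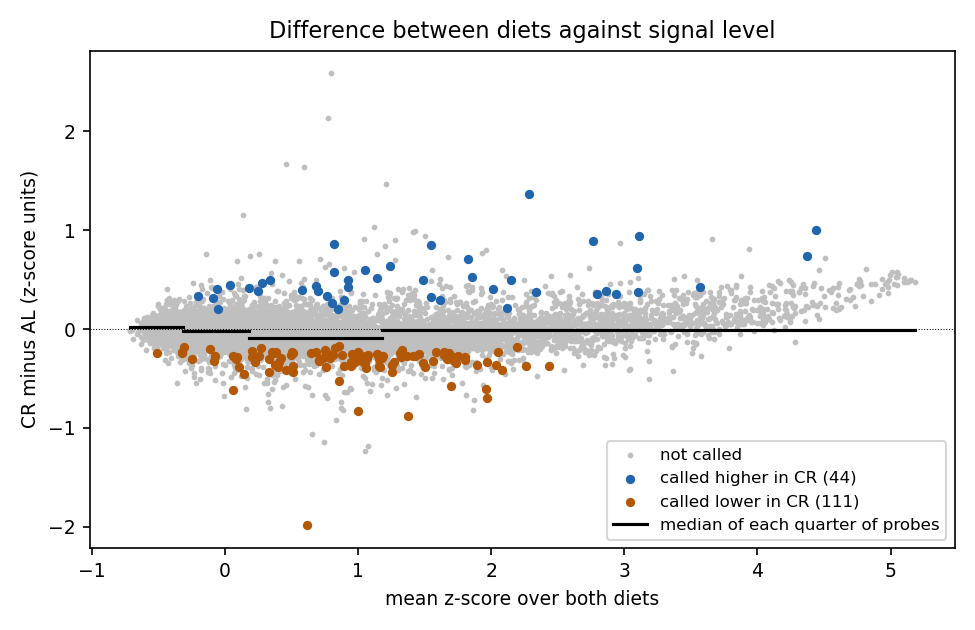
CR minus AL difference of each of the 11293 probes (vertical axis, z-score units) against its mean score over both diet means (horizontal axis), with the 44 probes called higher in CR in blue, the 111 called lower in orange and all others in grey. Black lines give the median difference in each of 4 equal-sized bins of probes by level, which was -0.09 in bin 3, and at mean scores above 4 nearly all points lie above 0.

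The difference between the diets varied with signal level. With the probes in 4 equal-sized bins from dim (bin 1) to bright (bin 4), the median CR minus AL difference was 0.02, -0.02, -0.09 and -0.01 in bins 1 to 4. Bin 3 held 59 of the 111 probes called lower and 16 of the 44 called higher. Among the 146 probes with a mean score above 4, the brightest on the array, 144 had higher means in CR, with a median difference of 0.33, and 2 were called. The median score of these 146 probes was 4.52 ± 0.15 in CR arrays and 4.24 ± 0.14 in AL arrays (SD, n = 5 each; exact permutation test, two-sided, p = 0.024). After quantile normalization, which gives every array the same distribution, 72 of the 146 were higher in CR and their median difference was -0.0014. With median centring and scaling by the median absolute deviation, all 146 were higher. Their median difference of 0.97 was in units set by each array's median absolute deviation, so its size does not compare with the others. Without AL array 10, on the deposited scores, 144 were higher, with a median difference of 0.25. In bin 3, quantile normalization gave 19 calls higher and 9 lower, with a median difference of -0.02.

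The 12 largest called differences without overlap ranged from 0.58 to 1.37 among probes higher in CR and from 0.43 to 1.99 among probes lower in CR. Uncalled probes, left out here, differed by up to 2.59. Among the called probes without overlap, the largest increase was at row 6513. It scored 2.97 ± 0.33 in CR and 1.6 ± 0.37 in AL (SD, n = 5 each). Its difference was 1.37 ± 0.19 (SE), with a limma adjusted p of 0.012. Its mean rank rose from the 81st to the 95th percentile of the listed probes. Next was row 3641, one of the brightest probes, with 4.94 ± 0.32 in CR and 3.94 ± 0.40 in AL, a difference of 1.00 ± 0.20 (SE; limma adjusted p = 0.043). It lay in the range above 4 where almost all probes were shifted upwards, and after quantile normalization its difference was 0.73 with an adjusted p of 0.080.

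Among the called probes without overlap, the largest decrease in score was at row 5800. It scored -0.37 ± 0.11 in CR and 1.61 ± 1.01 in AL (SD, n = 5 each). Its difference was -1.99 ± 0.39 (SE), with a limma adjusted p of 0.043. The SE and adjusted p assume 1 variance for both diets, which the SDs of 0.11 and 1.01 at this row do not bear out. All 5 CR animals scored between -0.51 and -0.24, while the AL animals spread from 0.25 in array 6 to 3.05 in array 7. If the scores were standardised over all rows, 2 of the 5 CR values lay within 1 SD of the implied mean of the blank rows and none lay over 3 SD above it. The CR level is therefore not shown to be above background, and the size and rank of this difference are not exact. After quantile normalization its difference was -2.01 with an adjusted p of 0.053. Row 17486 fell from 1.81 ± 0.34 in AL to 0.93 ± 0.14 in CR, a difference of -0.88 ± 0.15 (SE; limma adjusted p = 0.022). Row 6513 passed the threshold without any one of the arrays, with adjusted p up to 0.04998 (limma). Row 3641 missed it without CR array 2, 3, 4 or 5 or AL array 7, 8 or 9, with differences between 0.84 and 1.12 over all 10 removals and adjusted p up to 0.11. Row 5800 missed it without any one of the CR arrays or AL array 8 or 9 (-2.33 to -1.63, adjusted p up to 0.11), and row 17486 without CR array 2, 3 or 4 or AL array 7 or 9 (-0.99 to -0.78, adjusted p up to 0.073).

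**Figure D3:**
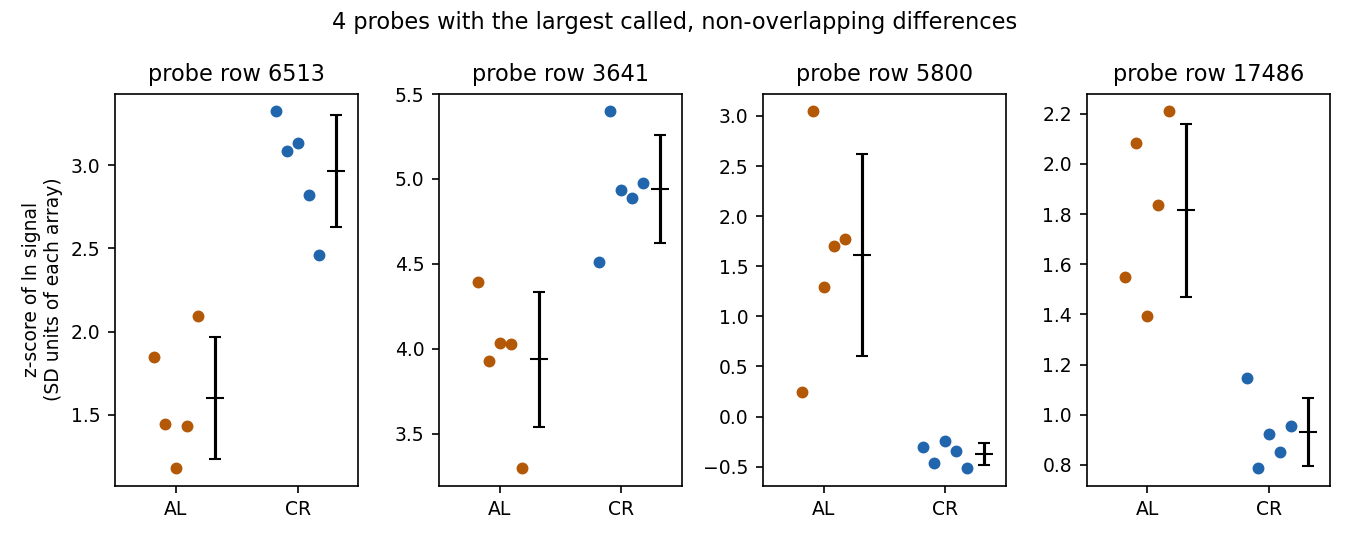
Score of each animal (vertical axes, z-score units, scaled separately and not starting at 0), with AL in orange and CR in blue. Among called probes without overlap, rows 6513 and 3641 had the 2 largest increases. Rows 5800 and 17486 had the 2 largest decreases among them. Points are the 5 animals of each diet and bars the mean ± SD, and at row 5800 the 5 CR animals sit between -0.51 and -0.24 while the AL animals reach 3.05.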

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

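The tests of AL array 10 and of the split of calls below were chosen after the result was seen, apart from the first label test, and the count of other divisions of the arrays was set beforehand. Of 18 groups of 5 values examined, 2 had a member far from the rest, where chance gives about 1 in 20. Both were mean correlations with the animal's own diet: 0.978 for CR array 5, against 0.985 to 0.987 for the other CR arrays, and 0.969 for AL array 10, against 0.982 to 0.986 for the other AL arrays.

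AL array 10 lay over 1 unit above the mean of the other AL arrays at 36 probes and over 1 unit below it at 53, and CR array 5 lay over 1 unit above the other CR arrays at 75 probes and below them at 3. A first test of a swapped diet label on AL array 10, with bounds set beforehand, fell between them: 39.9% of the 258 probes called without it lay nearer the CR mean, against 45.1% for CR array 5 and at most 28.7% for the others. A replacement test, chosen after that result, argued against a swap within the series, since calling the array CR gave 61 calls and exchanging it with a CR array at most 24, against 155 as labelled. After quantile normalization the mean correlation of AL array 10 with the other AL arrays was 0.970. The lowest of the other 9 arrays had 0.979 with its own diet. This argued against the shape of the score distribution of AL array 10 as the source. Pearson's r does not change with an array's mean or SD, so scaling by these could not be tested this way. Noise in dim probes was argued against too. The deviations of AL array 10 were 1.96 times those of the other AL arrays in the brightest of 4 level bins and 1.40 times in the dimmest. A swap with a sample outside the series, and a difference of that animal or its RNA, stay open and untested.

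The number of called probes was well above that of other divisions of the same arrays. Of 100 splits of the 10 arrays into 5 and 5, the real one included, 1 gave as many calls, the real one with 155, and the highest of the others drawn gave 9. Among the divisions not drawn, exchanging AL array 10 with CR array 1 gave 24. With quantile normalization the real split gave 81 calls and the highest of the others drawn 4. This argues against a chance division as the source of the call count. Not all 126 divisions were run, so chance is not excluded.

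More probes were called lower than higher in CR with the deposited scores, 71.6% of the calls. AL array 10 alone was argued against, since 72.9% of the calls were lower without it. The split depended on the scaling: with the same 10 arrays and the same variance model, the share was 50.6% after quantile normalization. Whether the authors' z-score scaling made the excess of lower calls, or quantile normalization removed a true shared shift, cannot be told apart. The share also fell with fewer arrays. With the deposited scaling kept it was 47.8% without CR array 2, 52.8% without CR array 4 and 56.1% without AL array 9. It was 54.9% with a trend and robust prior, but 67.7% with array weights and 73.2% without AL array 8. On the same arrays, quantile normalization lowered the share from 72.9% to 53.9% without AL array 10. Without CR array 5 and AL array 10 the share fell from 64.3% to 44.5% with quantile normalization. Quantile normalization, median centring (42.9%) and cyclic loess (41.6%) also remove, by construction, part of any shift that many probes share. Standardising each array by its own mean and SD, as in the deposited scores, removes part of such a shift too. With median centring and MAD scaling the share was 28%. Among the 146 probes above a mean score of 4, 144 were higher in CR with the deposited scores, 72 after quantile normalization and all 146 after median centring with MAD scaling. A true diet effect on the level of many probes stays open and untested.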

How the results depend on the processing

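The direction of each of the 4 identified probes and the excess of within-diet over between-diet correlation held under each alternative run for them, while the number of calls did not. For the 4 probes this direction was largely fixed by their choice. Since their diets did not overlap, leaving out or weighting arrays could not reverse it. Other variance models and the level filter left the differences unchanged, so only the changes of scaling tested the direction. Calls numbered 155 (44 higher, 111 lower in CR) in the main test. They numbered 81 (40 and 41) with quantile normalization, 56 (32 and 24) with median centring, 25 (18 and 7) with median centring and MAD scaling, 71 (29 and 42) with an intensity trend, 91 (41 and 50) with a trend and robust prior, 804 (260 and 544) with array weights and 48 (17 and 31) with the unmoderated statistic. Probes above the median level gave 138 (45 and 93). Leaving out 1 array gave 23 to 258 calls, 12 to 70 higher and 11 to 188 lower, lowest without CR array 2 and highest without AL array 10; the cause was not tested. At adjusted p under 0.10 there were 801 calls, under 0.01 there were 5, and 2546 probes had an unadjusted p under 0.05. Of the alternatives chosen after seeing the data, cyclic loess gave 89 (52 and 37), removing CR array 5 and AL array 10 gave 462 (165 and 297), the same with quantile normalization 337 (187 and 150), and quantile normalization without AL array 10 gave 191 (88 and 103). All 155 calls remained with array weights, 132 without AL array 10 and 74 with quantile normalization. Of 22 alternatives, the call was lost in 1 at row 6513, 12 at row 3641, 14 at row 5800 and 6 at row 17486. A filter on probes with missing values removed none, so it tested nothing. Tests of gene lists were not run because rows carry no gene names. No paired analysis was possible because the diets share no replicate numbers. No measured background signal was used here. The floor of dim probes was placed only at the implied level of the blank rows, on the assumption of scores standardised over all rows.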

Other observations

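The set of probes below was noticed in the data, and its tests were set before their results were seen, apart from the check of the spread that the choice of probes fixes. The probe with the largest CR minus AL difference in score was not called (2.59 ± 0.96 SE; limma adjusted p = 0.15), because the CR animals were divided. It scored 4.53 in CR array 2, 4.21 in CR array 5 and 2.77 in CR array 3, but -0.65 in CR array 1, -0.38 in CR array 4 and between -0.64 and -0.07 in the 5 AL arrays. On the assumption of scores standardised over all rows, 4 of the 5 AL values and 1 of the 5 CR values lay no more than 1 SD above the implied mean of the blank rows, so the low values are not shown to be above background and the size and rank of the difference are not exact. In CR arrays 2 and 5 it ranked above the 99th percentile of the listed probes. With 8 other probes following it over the 10 arrays (r of at least 0.95), among those with a range of at least 1, this set had median scores of 2.44, 1.40 and 2.80 in CR arrays 2, 3 and 5 and from -0.44 to -0.19 in the other 7. Of 1000 random orders of the lead probe's values, a share of 0.005 gave 8 or more followers, with 9 as the most. The lead probe and its set were picked from these same data, and the share does not allow for that choice. It therefore does not decide whether chance correlation explains the set. Whether the set comes from one source of RNA in different amounts was left undecided. The steps of the 9 probes between arrays 2 and 3 ran from 0.39 to 2.10 with an SD of 0.64, but choosing probes by their correlation with the lead probe already fixes such a spread, at an SD of 0.53, so the test decides nothing.

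The spread between animals looked wider in AL, with the larger SD at 60.2% of probes, but this rested on AL array 10. Without it and one CR array the share lay between 45.6% and 54.2%.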
